A study of Mus musculus and Rattus norvegicus with 42 samples.

How the data were processed

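RNA sequencing was read from 2 deposited tables of raw counts. The first held 36 libraries of pancreatic islets from C57BL/6 mice aged 20 weeks. The second held 6 libraries of INS-1 832/13 cells, a rat insulinoma line used as a model of the insulin-secreting beta cell. Both tables gave raw counts per gene symbol, as deposited by the authors. Per the labels' protocols, libraries were made from 100 ng of total RNA by selection of polyadenylated RNA. Per the submitters' processing notes, HISAT2 2.1.0, featureCounts 2.0.0 of the Subread package and edgeR 3.28.1 were used with the genome builds mm10 for mouse and rn6 for rat. Whether reads were counted by strand, and which annotation was used, are not given in the sources used here. Genes that overlap on opposite strands, such as Oip5-as1 and its neighbour, were therefore not told apart. Members of near-identical families, such as the pancreatic amylases Amy2a5 and Amy2b, can share reads and are reported as uncertain.

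The islet table had 24421 lines with 24419 distinct symbols, and 24019 of them (98.4%) matched a gene of GENCODE release M21, which is built on GRCm38 (mm10). Mouse coordinates came from that annotation. The INS-1 table had 17455 lines and no rat coordinates are given. No count was found in any library for 4340 genes of the islet table and 3105 genes of the INS-1 table. A total of 27 lines were named by a number in place of a symbol and held 0.14% of the counts. All columns were matched to samples by name.

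Total counts per islet library ranged from 20.1 to 31 M with a median of 23.8 M. Totals per INS-1 library ranged from 36.4 to 49.7 M with a median of 39.2 M.

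Groups were taken from the labels: CON, CD and CD-tRF for islets, with 12 libraries each, and scramble or Dbp siRNA for INS-1 cells, with 3 libraries each. Each islet group had 2 libraries at each of 6 circadian times at 4 h steps. The labels do not say whether the 2 libraries of a group and time came from separate animals, or whether the 3 INS-1 libraries of a group came from separate cultures. The p-values therefore reflect only the spread between these libraries, which may be technical.

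Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr, which left 14454 genes in islets and 11713 genes in INS-1 cells, and libraries were scaled by TMM. Group means were compared by the quasi-likelihood F-test with robust dispersion in a model of group and circadian time as a 6-level factor, fitted to all 36 islet libraries. Rhythms were tested in a model with a mean, a cosine and a sine term of 24 h period per group. A gene was called rhythmic by the joint test of its cosine and sine terms, and rhythms were compared between groups by the joint test of the difference of those terms. Amplitude is given on the log2 scale as the distance from the mean to the peak. INS-1 groups were compared in the same way without further terms. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, at an FDR of 0.05. Every adjusted p of a gene is from edgeR unless another tool is named. The log2 CPM values behind the acinar score and the length slope, defined below, used a prior count of 1. Fold changes and amplitudes came from the model fit at the default of edgeR. Errors of fold changes and amplitudes are standard errors, while errors of CPM values, computed from the deposited counts, are SDs.

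Gene lists for the clock, beta cell function, metabolism, stress responses, other cell types and controls were fixed before the data were examined, together with the tests, the alternatives and the rule for naming genes. For each list the number of called members is given over all genes tested and adjusted over the list alone. Lists with at least 5 tested members were compared with other genes by camera in limma with a preset correlation of 0.01 between genes, and again with an estimated correlation. In fry, the directional p tests whether a list's genes move on balance one way, and the mixed p whether they change in either direction. Neither compares a list with other genes. The excess of rhythmic genes in a list was tested by Fisher's exact test against all genes tested. This test treats genes as independent, so its p can be too small where the genes of a list move together.

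The named genes were, in each group comparison, the 10 higher and the 10 lower genes with the smallest p among those called, with a mean log2 CPM of at least 2 and no predicted gene models. All core clock genes were named, with up to 4 genes of smallest p in any other list discussed, and 10 genes outside the clock list for each rhythm test and each rhythm difference. Dbp was given first for every siRNA library. A list member that did not pass could be named with its value. Genes named outside this rule are said to have been chosen after their values were seen.

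The steps were tested on simulated counts in which 50 genes per size were changed. Counts were drawn separately for each library, without a level shared by the 2 islet libraries of a group and time. In the data the correlation of these 2 libraries, a consensus over genes, was 0.48 around the group means. The shares and false calls given here do not cover that shared level. At the depth and replication of the CD and CON libraries, the model called 46% of genes changed 1.25-fold, 96% of those changed 1.5-fold, 96% of those changed 2-fold and 100% of those changed 3-fold. Of 14401 genes tested 7 others were called. In the simulation of rhythm in CON, 26% of genes with a log2 amplitude of 0.25 were called, 74% at 0.5, 96% at 1 and 100% at 1.5. Of 14407 genes tested 8 others were called, and the median error of the peak was 0.17 h. For a rhythm difference between CD and CON the shares were 8%, 42%, 94% and 100% at the same amplitudes. In the simulated INS-1 comparison, 62%, 90%, 100% and 100% of genes changed 1.25-, 1.5-, 2- and 3-fold were called.

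The alternatives fixed in advance were RLE scaling, other filters on low counts, DESeq2 1.42.0, replicate numbers as a block, leaving out libraries, replicate numbers or times, and an acinar score as a covariate. Further ones were other time terms, fits to fewer groups, splits of the CD libraries, an estimated correlation and fry for lists, and a test against a 1.5-fold change for INS-1 cells. The acinar score was the mean log2 CPM of the acinar marker list. Alternatives chosen after seeing the data were summing the 2 libraries of each group and time, leaving out 3 libraries that stood apart by more than 3 MADs in their transcript length slope, and that slope as a covariate. Also chosen then were leaving out the CD pair of 8 h, alone or with the pairs summed, splitting the CD libraries by time, and the list tests under such settings. The length slope of a library is the slope of its log2 CPM, relative to the mean of all islet libraries, on log2 transcript length, which was known for 99.2% of the tested genes. Lists and figures were compiled with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.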

Results

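Gene expression was measured by RNA sequencing in pancreatic islets from mice of 3 groups and in a rat beta cell line. The islet groups were an untreated control (CON), mice kept for 8 weeks under constant light as circadian disruption (CD), and mice under the same light whose food was given only within an 8 h window (CD-tRF). Islets were collected at 6 circadian times from 0 to 20 h, with 2 libraries per group and time and 12 libraries per group. Total counts were 20.1 to 31 M per library in CON (median 24.3 M), 20.8 to 28.2 M in CD (median 22.6 M) and 20.7 to 26.6 M in CD-tRF (median 23.8 M). INS-1 832/13 cells, an insulinoma line used as a stand-in for the beta cell, were transfected with scramble siRNA or with siRNA against Dbp, a clock-driven transcription factor, with 3 libraries each and 36.4 to 49.7 M counts per library.

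The insulin transcripts Ins1 and Ins2 took 22.5% ± 3.26 of the counts in CON, 21% ± 5.11 in CD and 23.8% ± 6.51 in CD-tRF (SD, n = 12 each). Transcripts of the acinar cells of the exocrine pancreas took 0.193% to 0.784% of the counts in CON, 0.0318% to 1.68% in CD and 0.0166% to 0.586% in CD-tRF. The 2 libraries of a group and time resembled each other: 29 of the 36 libraries correlated best with the other library of their group and time, and the acinar score had an intraclass correlation of 0.99 within pairs. Averaged per pair, the acinar score was 6.08 ± 0.92 in CON, 6.64 ± 2.26 in CD and 3.99 ± 2.28 in CD-tRF (log2 CPM, SD, n = 6 times). Differences of this score between groups did not pass a two-sided exact permutation test (p = 0.0714 for CD-tRF against CD, 0.0584 for CD-tRF against CON and 0.632 for CD against CON, with adjusted p = 0.107, 0.107 and 0.632). Relative to the other libraries, long transcripts were low in CD CT8-1 (length slope -0.31), CD CT8-2 (-0.27), CD-tRF CT16-1 (-0.29) and CD-tRF CT4-2 (-0.39), and the last of these had the highest insulin share of 39.9%.

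**Figure D1:**
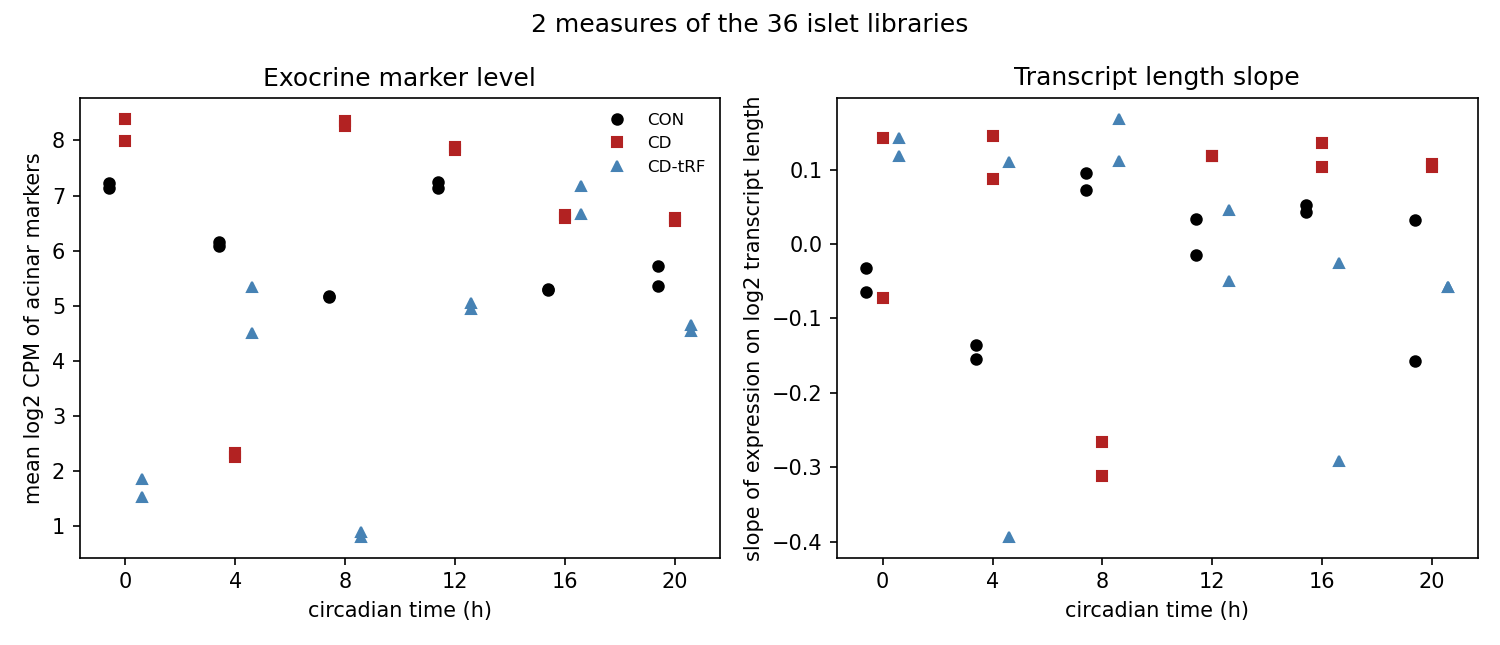
Mean log2 CPM of the acinar markers and slope of relative expression on log2 transcript length, per islet library, against circadian time in h. Points are single libraries of the 3 groups. The 2 libraries of a group and time lie close together in acinar level, and CD-tRF CT4-2 has the lowest length slope of -0.39.

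The first question was how the daily rhythm of gene expression in islets differed between the groups. In CON islets several clock genes cycled with large amplitudes (n = 12 libraries per group). Arntl (mm10 chromosome 7, 113207465 to 113314126), which encodes the activator BMAL1, had an amplitude of 1.40 ± 0.12 in CON, 0.29 ± 0.11 in CD and 2.08 ± 0.12 in CD-tRF. Its peak lay at 22.2 h in CON and 23.2 h in CD-tRF. Npas2 (chromosome 1, 39193731 to 39363236), which encodes a further partner of BMAL1, had a fitted cosine that spanned 22.6-fold from trough to peak in CON and 49.3-fold in CD-tRF. At 12 h its 2 libraries were at 0.158 and 0.238 CPM in CON and 0.383 and 0.215 CPM in CD-tRF. Both spans therefore rest on few counts at the trough. The amplitudes of Npas2 were 2.25 ± 0.14 in CON, 0.50 ± 0.12 in CD and 2.81 ± 0.15 in CD-tRF. Nr1d1 (chromosome 11, 98767932 to 98775333), the gene of the repressor REV-ERB alpha, had amplitudes of 1.58 ± 0.14, 0.13 ± 0.14 and 1.68 ± 0.14 in the same order, and peaked at 5.3 h in CON and 6.4 h in CD-tRF. Dbp (chromosome 7, 45705088 to 45710203), which encodes a clock-driven transcription factor of the PAR bZip family, spanned 9.51-fold by its fitted cosine in CON and 9.53-fold in CD-tRF, and its amplitude in CD was 0.49 ± 0.21.

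Several repressors of the clock loop also had their smallest amplitude in CD. Per2 (chromosome 1, 91415982 to 91459324) had amplitudes of 0.84 ± 0.13 in CON, 0.32 ± 0.14 in CD and 0.87 ± 0.13 in CD-tRF. Cry1 (chromosome 10, 85131700 to 85185064) had 1.00 ± 0.09, 0.15 ± 0.09 and 0.93 ± 0.09. Per3, with amplitudes of 1.29 in CON, 0.39 in CD and 1.26 in CD-tRF, and Nfil3, a repressor that binds the same DNA sites as DBP, with 1.54, 0.40 and 1.77, gave further examples. Cry2 did not, with amplitudes of 0.39 in CON, 0.45 in CD and 0.32 in CD-tRF. Of 19 measured core clock genes, 15 were rhythmic in CON (16 adjusted over the list alone) and 17 in CD-tRF (19 adjusted over the list alone). In CD, 0 passed over all genes with edgeR, against 7 adjusted over the list alone, 10 at an unadjusted p under 0.05 and 2 with DESeq2. With the acinar score as a covariate 8 clock genes passed in CD, and with the length slope as a covariate 3. With time as a 6-level factor, a test of any difference between times, 16 of 19 passed in CD, Nr1d1 among them (adjusted p = 8.79e-09). That test sets the times against the spread within pairs of libraries, and it called far more genes in CD than the cosine did. A level shared by a pair for another reason would pass it too. The lack of a called 24 h cosine in CD does not by itself show a constant level, and whether these genes varied over the day there stays open. Clock, Cry2, Rora and Bhlhe41 were not called rhythmic in CON (adjusted p = 0.54, 0.151, 0.484 and 0.443), and Rora and Bhlhe41 were called in CD-tRF (adjusted p = 0.00421 and 0.000289).

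The difference of rhythm itself was called for 15 of 19 clock genes between CD and CON (16 adjusted over the list alone) and for 17 between CD-tRF and CD (18 adjusted over the list alone). Examples of the adjusted p for CD against CON were 1.11e-06 for Arntl, 6.38e-10 for Npas2, 7.18e-06 for Nr1d1, 0.000711 for Dbp and 0.000384 for Cry1. For CD-tRF against CD they were 1.7e-10 for Arntl, 4.7e-12 for Npas2, 1.27e-06 for Nr1d1, 9.43e-05 for Dbp and 0.000281 for Cry1. Between CD-tRF and CON 0 clock genes passed with edgeR, with 1 adjusted over the list alone (Arntl, adjusted over all genes p = 0.128), 7 at an unadjusted p under 0.05 and 1 with DESeq2. Adjusted over the list alone, 9 passed in this comparison with the acinar score as a covariate (1 over all genes), 10 with the length slope as a covariate, 4 without 3 libraries and 5 without the CD pair of 8 h. The clock list held more called genes than other genes did among those rhythmic in CON (Fisher's exact test, adjusted p = 7.39e-17) and in CD-tRF (1.33e-12). It also did among those whose rhythm differed between CD and CON (3.73e-22) and between CD-tRF and CD (2.9e-15). With the 2 libraries of each group and time summed, 3, 0 and 9 clock genes were rhythmic in CON, CD and CD-tRF over all genes, against 15, 0 and 17 adjusted over the list alone. The rhythm difference was then called for 1 clock gene between CD and CON and for 3 between CD-tRF and CD, against 15 and 17 adjusted over the list alone. In these sums the adjusted p over all genes for CD against CON was 0.0108 for Npas2, 0.127 for Arntl, 0.434 for Nr1d1 and 0.769 for Dbp and for Cry1.

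**Figure D2:**
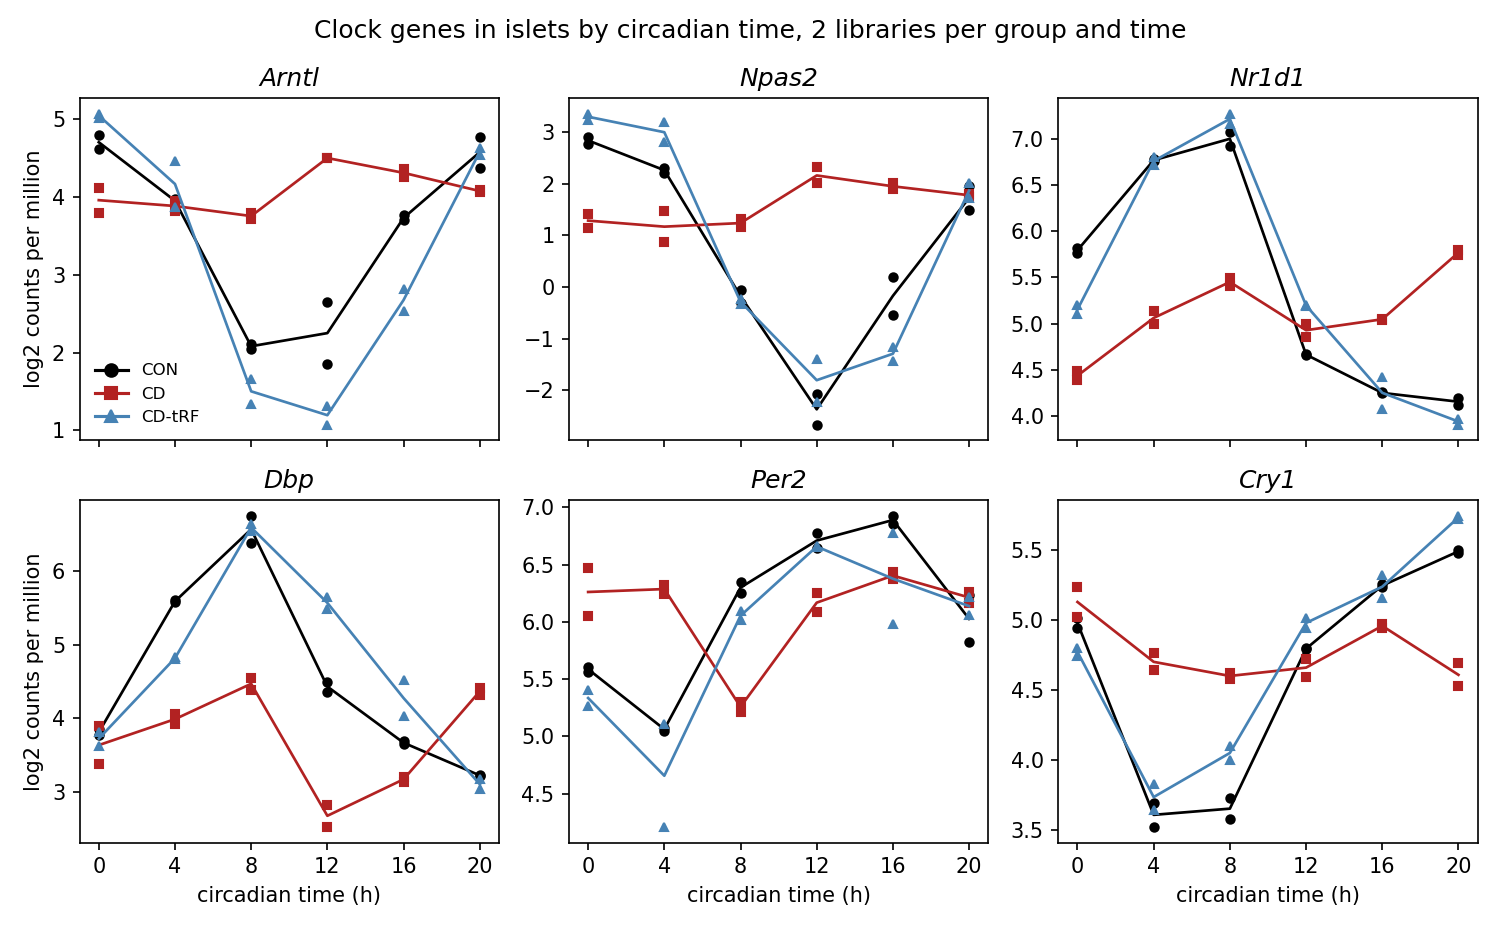
Log2 CPM of Arntl, Npas2, Nr1d1, Dbp, Per2 and Cry1 against circadian time in h in the 3 islet groups. Points are single libraries and lines join the means of the 2 libraries of a group and time. The curves of CON and CD-tRF rise and fall together and the CD curves are flatter, with fitted amplitudes of Npas2 of 2.25 in CON, 0.50 in CD and 2.81 in CD-tRF.

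**Figure D3:**
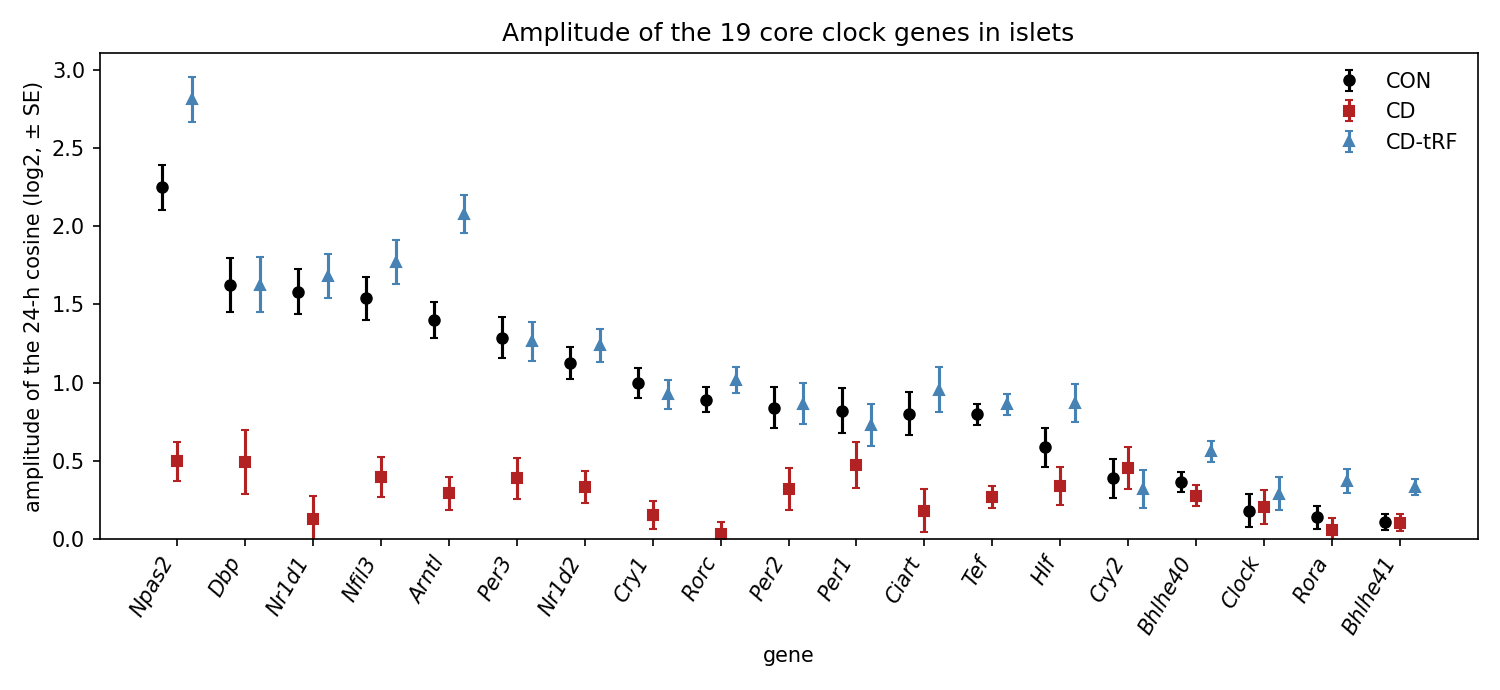
Fitted log2 amplitude of the 19 core clock genes in CON, CD and CD-tRF. Error bars are standard errors from the fit to all 36 libraries. The CD amplitude of Npas2 is 0.50 against 2.25 in CON and 2.81 in CD-tRF.

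Outside the clock list, Ppp1r3c (chromosome 19, 36731731 to 36736653), which encodes a subunit that directs protein phosphatase 1 to glycogen, had amplitudes of 1.18 ± 0.10 in CON, 0.31 in CD and 1.68 ± 0.10 in CD-tRF. Its rhythm differed between CD and CON (adjusted p = 2.21e-07) and between CD-tRF and CD (9.28e-11). The phosphatase gene Ppm1b, the endocytosis adaptor gene Hip1r, the metalloproteinase inhibitor gene Timp3 and the acid-sensing channel gene Asic2 were among the genes with the smallest p in CON, with amplitudes of 0.44, 0.45, 0.63 and 0.79. In CD-tRF the 10 genes with the smallest p included Slc41a3, a gene of the magnesium carrier family, whose fitted cosine spanned 7.92-fold with a peak at 1.7 h, Cmpk2, which encodes a mitochondrial nucleotide kinase (amplitude 0.86), and Fam84a (1.06). In all, 567 of 14454 genes were rhythmic in CON, 45 in CD and 1773 in CD-tRF (3.92%, 0.311% and 12.3%), with 393 rhythmic in both CON and CD-tRF against 69.6 for independent lists. The order of CON and CD-tRF depended on the fit, since fits to each group alone gave 2132, 13 and 597 genes. Time as a 6-level factor, which tests any difference between times against the spread within pairs, called 2592, 8046 and 5183. The peak of those 393 genes in CD-tRF minus that in CON had a median of -0.5 h, with quartiles of -1.4 and 0.5 h.

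Of the 45 genes rhythmic in CD, 14 were also rhythmic in CON (1.77 for independent lists) and 18 in CD-tRF (5.52). As many genes were rhythmic in CD in 42 of 60 orders of the times, so chance cannot be excluded for this count. Without CD CT8-2 the count was 15. With the pairs summed, the rhythms in CD and the rhythm differences of the genes named below were not called. Tnfaip3 (chromosome 10, 19000910 to 19015657), which encodes the NF-kB inhibitor A20, had an amplitude of 1.39 ± 0.14 in CD with a peak at 17.4 h, against 0.18 ± 0.14 in CON and 0.14 ± 0.14 in CD-tRF. The adjusted p of the difference was 4.43e-05 against CON and 7.89e-05 against CD-tRF. Nfkbia, which encodes the inhibitor that holds NF-kB in the cytoplasm, had amplitudes of 1.12 ± 0.15 in CD, 0.21 in CON and 0.19 in CD-tRF (0.00108 and 0.00144). Errfi1, an inhibitor of the EGF receptor, had 0.90 ± 0.12 in CD, 0.29 in CON and 0.21 in CD-tRF (0.0368 and 0.00195). Cited2, a transcriptional coregulator, cycled in every group but peaked at 17.5 h in CD, 4.6 h in CON and 1.9 h in CD-tRF (adjusted p of the difference 2.21e-07 and 1.72e-07). Gadd45b, a stress-induced gene, peaked at 17.9 h in CD and 5.7 h in CON with nearly equal amplitudes of 0.89 and 0.88. The arrestin-family genes Txnip and Arrdc4, both induced by glucose, each had an amplitude of 0.59 in CD with a peak at 17.8 h.

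By list, 3 of 12 measured cytokine and NF-kB response genes were rhythmic in CD (3 adjusted over the list alone, Fisher's exact test with adjusted p = 0.000156), against 4 in CD-tRF (5 adjusted over the list alone, 0.205). Further, 3 differed in rhythm between CD and CON (3 adjusted over the list alone, 0.0173) and 6 between CD-tRF and CD (7 adjusted over the list alone, 0.0037). In CD-tRF, 12 of 18 heat shock genes were rhythmic (17 adjusted over the list alone, 1.68e-06), against 2 in CON (7 adjusted over the list alone, 11 at an unadjusted p under 0.05, 0.51) and 1 in CD (2 adjusted over the list alone). The rhythm difference between CD-tRF and CON was called for 0 of these 18 genes with edgeR (4 at an unadjusted p under 0.05). Between CD-tRF and CD 7 differed in rhythm (10 adjusted over the list alone, 0.00487). Of 23 genes of beta cell identity, 10 were rhythmic in CD-tRF (13 adjusted over the list alone, 0.00208) and 3 in CON (8 adjusted over the list alone, 0.28). Of these 23 genes 7 differed in rhythm between CD-tRF and CD (12 adjusted over the list alone, 0.0193) and 0 between CD-tRF and CON with edgeR (2 at an unadjusted p under 0.05). Further lists that passed in CD-tRF were ER stress with 10 of 26 genes (11 adjusted over the list alone, 0.00512) and fatty acid genes with 9 of 28 (14 adjusted over the list alone, 0.0317). Of 20 FoxO and glucocorticoid targets, 5 were rhythmic in CON (8 adjusted over the list alone, 0.0143) and 7 in CD-tRF (7 adjusted over the list alone, 0.0412). With the pairs summed, neither a rhythm nor a rhythm difference was called over all genes for any member of the lists in this paragraph. Fisher's exact test treats genes as independent, while heat shock genes, for example, had an estimated correlation of 0.52 in CD against CON. Its p-values can therefore be too small. The 3 cytokine genes in CD also belong to a total of 45 that was reached in 42 of 60 orders of the times.

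Rhythm differed between CD and CON for 254 genes, with the smaller amplitude in CD for 196 of them, and between CD-tRF and CD for 1233 genes, with the larger amplitude in CD-tRF for 1037. Of the 567 genes rhythmic in CON, 392 (69.1%) had less than 0.5 times their CON amplitude in CD and 66 (11.6%) in CD-tRF, with median amplitudes of 0.37 in CON, 0.14 in CD and 0.34 in CD-tRF. These genes were picked for their rhythm in CON, which favours a high amplitude there. Between CD-tRF and CON the rhythm of 4 genes differed, a count that ran from 0 to 9 when single libraries were left out. Stk40, a kinase-like gene, peaked at 14.3 h in CD-tRF and 17.7 h in CON (amplitudes 0.42 and 0.23, adjusted p = 0.0243), and Apobec1, an RNA-editing cytidine deaminase gene, at 20 h and 5.0 h (0.0481). The call of Apobec1 was lost in most alternatives. The remaining 2, chosen after their values were seen, were the low-level genes Syce1 (0.0243) and Gm20751 (0.0481). With the pairs summed, 4, 0 and 34 genes were rhythmic in CON, CD and CD-tRF (760, 397 and 1591 at an unadjusted p under 0.05). With the same sums 1, 5 and 0 differed in rhythm between CD and CON, CD-tRF and CD, and CD-tRF and CON (587, 1187 and 127 unadjusted). The 4 in CON were Npas2, Ppp1r3c, Arntl and Nfil3. Without CD-tRF CT4-2 the rhythm difference between CD-tRF and CD was called for 6797 genes and the rhythm in CD-tRF for 4950. In CD, 2896 genes were rhythmic with the acinar score as a covariate and 13 without the CD pair of 8 h.

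The comparison of CD with CON asked how constant light changed the mean level of genes over the day. Rgs2 (chromosome 1, 143999338 to 144004161), a regulator of G protein signalling, was 4.84-fold higher in CD, at 233 ± 139 CPM against 47.9 ± 23.5 CPM (SD, n = 12 each, log2 change 2.28 ± 0.33, adjusted p = 0.000232). Errfi1 (chromosome 4, 150853919 to 150868892) was 2.55-fold higher, at 76.7 ± 38.3 against 28.3 ± 4.65 CPM (2.57e-05), and Sox4 (chromosome 13, 28948919 to 28953713), a transcription factor of islet development, rose from 33.0 to 63.1 CPM (0.000108). Ctgf (chromosome 10, 24595442 to 24598683), a secreted matricellular protein, was higher by 0.75 ± 0.10 on the log2 scale and the Hippo pathway coactivator Yap1 by 0.39 ± 0.07. Lower in CD were Neurog3 (chromosome 10, 62133090 to 62134763), the transcription factor of endocrine progenitors, by -0.58 ± 0.11, and Srebf1 (chromosome 11, 60199089 to 60222581), a regulator of lipid synthesis, by -0.32 ± 0.06. The polycomb gene Cbx8 (-0.39) and Alas1 (-0.29), the first enzyme of haem synthesis, were lower too. The 12 libraries of a group formed pairs of like libraries, with a consensus correlation of 0.48, so these errors and p-values may be too small. None of the genes named in this paragraph passed with the pairs summed.

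Of 20 measured FoxO and glucocorticoid targets, 9 were higher in CD and 0 lower (12 and 0 adjusted over the list alone). They included Pdk4 (chromosome 6, 5483351 to 5496309), a kinase that restrains pyruvate oxidation (0.84 ± 0.17), Cdkn1a, a cell cycle inhibitor (0.58 ± 0.12), Klf9 (0.50 ± 0.10) and Tsc22d3, a glucocorticoid-induced gene (0.42 ± 0.09). The list passed camera (adjusted p = 1.66e-10) and passed with an estimated correlation (0.00386). Of 18 heat shock genes 5 were higher (12 adjusted over the list alone), with Hsph1 at 0.79 ± 0.17 and Chordc1 at 0.62 ± 0.14. For these genes camera gave an adjusted p = 8.58e-09, against adjusted p = 0.203 with an estimated correlation. Of 12 cytokine and NF-kB response genes 3 were higher (7 higher and 1 lower adjusted over the list alone): Nfkbiz, an inducible NF-kB cofactor that was 1.92-fold higher, Nfkbia (1.06 ± 0.23) and Nfkb2 (0.59 ± 0.12). That list had an adjusted p = 2.64e-05 by camera and an adjusted p = 0.0565 with an estimated correlation.

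Of 21 interferon response genes 3 were lower, Oasl2 (-0.39 ± 0.09), Irf7 (-0.58 ± 0.14) and Ifit3 (-0.79 ± 0.20), and 1 was higher, Irf9 at 0.25 ± 0.07 (1 higher and 6 lower adjusted over the list alone). The interferon list had a camera adjusted p = 0.000891, and adjusted p = 0.203 with an estimated correlation. Of 23 beta cell identity genes, 3 were lower: the homeobox gene Mnx1 (chromosome 5, 29473034 to 29478470) by -0.44 ± 0.09, Pdx1 (chromosome 5, 147269959 to 147275848), a regulator of the insulin gene, by -0.33 ± 0.07, and Pax6 by -0.14 ± 0.04. Adjusted over the list alone, 2 were higher and 3 lower, and the list did not pass camera (adjusted p = 0.0518). Ins1 and Ins2 had log2 changes of 0.04 ± 0.22 and -0.13 ± 0.19 (adjusted p = 0.941 and 0.755). The acinar markers moved beside these groups with a median of 1.16, and 0 of 26 passed with edgeR (3 at an unadjusted p under 0.05, camera adjusted p = 0.00304, adjusted p = 0.872 with an estimated correlation). Among clock genes, Cry2 was higher by 0.55 ± 0.13 (1 higher, or 3 higher and 1 lower adjusted over the list alone), and Cirbp, a cold-inducible RNA-binding protein (chromosome 10, 80165985 to 80172786), was lower by -0.38 ± 0.10.

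In total 486 genes (3.36%) passed, 296 higher and 190 lower, 95 of them by at least 1.5-fold. Leaving out CD CT8-1 or CD CT8-2 gave 1205 or 833 genes, leaving out both gave 5069, and leaving out CD CT0-1 or CD CT20-1 gave 277 or 304. With the pairs summed, 1 gene passed at an FDR of 0.05 and 1108 at an unadjusted p under 0.05, Btg3, an antiproliferative gene, at 2.18 (adjusted p = 0.00325, chosen after its values were seen). On the summed pairs camera called the FoxO and glucocorticoid targets (2.93e-09), the heat shock genes (4.1e-07) and the cytokine list (0.0163) at the preset correlation. With an estimated correlation over all libraries the heat shock and cytokine lists did not pass (0.203 and 0.0565).

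The comparison of CD-tRF with CD asked what the feeding window changed under constant light. Ctgf was lower in CD-tRF, with a fold of 0.505 (log2 change -0.99 ± 0.10, adjusted p = 3.57e-07, n = 12 each), and Errfi1 was lower by -1.26 ± 0.16 (1.05e-05). The chaperone genes Hspb8 (-0.75 ± 0.09) and Ahsa2, an HSP90 cochaperone gene (-0.91 ± 0.12), and the integrin gene Itga10 (-0.88) were also among the 10 lower genes with the smallest p. Higher in CD-tRF were Psmf1, a proteasome inhibitor (0.34 ± 0.04, 5.31e-06), Arhgap36 (chromosome X, 49463945 to 49500244, 0.57 ± 0.07, 1.05e-05), and the calcium sensor gene Vsnl1 (0.52 ± 0.08). The lipoxygenase gene Alox12 was higher by 0.58 and Rprml 2.17-fold. Of the genes named in this paragraph only Ctgf passed with the pairs summed.

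Of 20 FoxO and glucocorticoid targets 11 were lower in CD-tRF and 0 higher (12 lower adjusted over the list alone). Ddit4, an inhibitor of mTOR signalling, was at -0.77 ± 0.10, Cdkn1a at -0.77 ± 0.12 and Klf15 at -0.46 ± 0.10. Of 23 beta cell identity genes 6 were higher (6 adjusted over the list alone), among them Mnx1 (0.49 ± 0.09), Pdx1 (0.31 ± 0.07), the taste-type cation channel gene Trpm5 (0.34 ± 0.08) and Sytl4 (0.19 ± 0.05), a granule-docking protein gene. Both lists passed camera (adjusted p = 7.27e-08 and 0.00398) and passed with an estimated correlation (0.0174 each). These were, with the FoxO list in CD against CON, the calls of camera that held with an estimated correlation in any comparison. Of 18 heat shock genes 12 were lower (14 adjusted over the list alone), with Hsph1 at -0.95 ± 0.17 and Hspb1 at -0.89 ± 0.20. The heat shock list had a camera adjusted p = 2.13e-09, and adjusted p = 0.187 with an estimated correlation. Of 12 cytokine and NF-kB response genes 3 were lower (5 adjusted over the list alone), Nfkbiz (-0.93 ± 0.15), Nfkbia (-0.96 ± 0.23) and Tnfaip3 (-0.88 ± 0.27). The cytokine list had a camera adjusted p = 0.000137, and adjusted p = 0.087 with an estimated correlation.

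**Figure D4:**
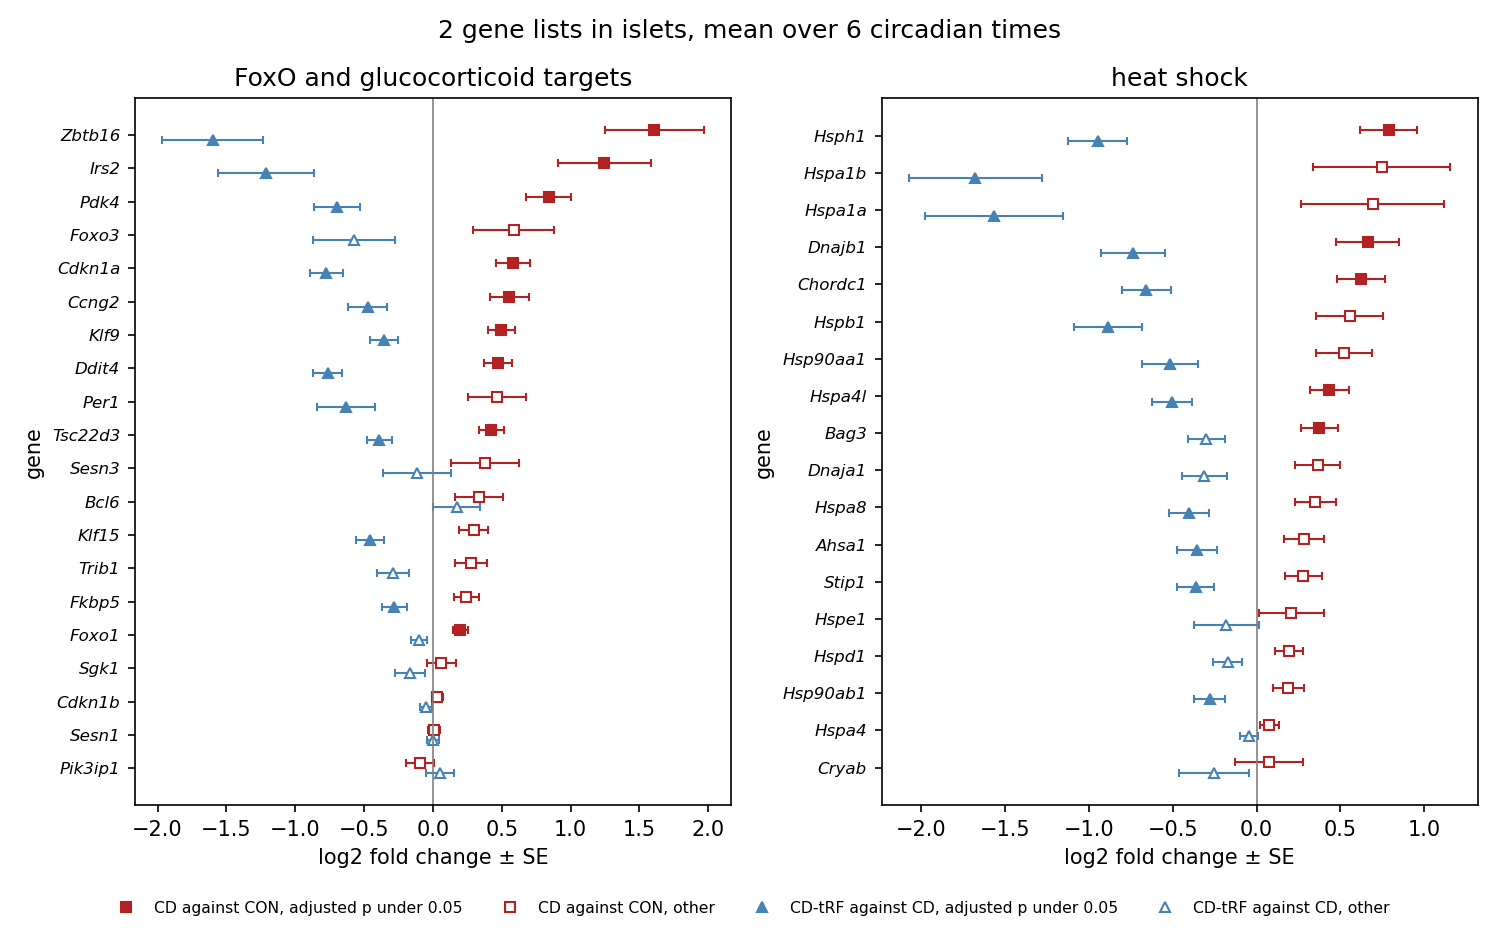
Log2 fold change of the FoxO and glucocorticoid targets and of the heat shock genes in CD against CON and in CD-tRF against CD. Error bars are standard errors and filled points passed at an FDR of 0.05. Of the FoxO list 9 were higher in CD than CON and 11 lower in CD-tRF than CD, and of the heat shock list 5 and 12.

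Members of several metabolic lists were higher in CD-tRF than in CD. Of 23 genes of cholesterol synthesis 7 were higher and 0 lower (11 adjusted over the list alone), with Hsd17b7 at 0.50 ± 0.10, Nsdhl at 0.41 ± 0.09 and Sqle, squalene epoxidase, at 0.28 ± 0.05. Cholesterol synthesis had a camera adjusted p = 5.97e-08, and adjusted p = 0.171 with an estimated correlation. Of 24 genes of the TCA cycle and pyruvate metabolism 5 were higher (6 adjusted over the list alone), including the mitochondrial citrate carrier Slc25a1 at 0.29 ± 0.08. The TCA cycle list had a camera adjusted p = 9.05e-06, and adjusted p = 0.187 with an estimated correlation. Of 18 glycolysis genes 4 were higher (7 adjusted over the list alone), including Pfkl, a subunit of phosphofructokinase, at 0.23 ± 0.06. The glycolysis list had a camera adjusted p = 0.0156, and adjusted p = 0.362 with an estimated correlation. The oxidative phosphorylation genes had a median of 0.24, and 0 of 35 passed with edgeR (6 at an unadjusted p under 0.05, camera adjusted p = 5.85e-06, adjusted p = 0.514 with an estimated correlation). Of 26 ER stress genes 4 were lower (8 adjusted over the list alone), led by Chac1 (-0.81 ± 0.13), which degrades glutathione, and Trib3 (-0.73 ± 0.14), a pseudokinase induced by amino acid stress. The ER stress list had a camera adjusted p = 0.00783, and adjusted p = 0.498 with an estimated correlation. Without the CD pair of 8 h, calls in this comparison followed transcript length. Genes higher in CD-tRF than in CD then had a median of 1.88 kb and those lower 4.66 kb, and 34 of 35 oxidative phosphorylation genes were higher. Whether transcript length had a part in the shifts of these lists with all libraries stays open.

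Beside these groups, 19 of 26 acinar markers were lower in CD-tRF (25 adjusted over the list alone), with a median of -2.47 and the amylase Amy2b at -3.09 ± 0.77, a value that is uncertain since Amy2a5 can share its reads. The acinar list had a camera adjusted p = 7.14e-16, and adjusted p = 0.216 with an estimated correlation. On the summed pairs 0 acinar markers passed with edgeR. With the acinar score as a covariate the FoxO and cholesterol lists passed camera at the preset correlation (adjusted p = 0.00111 and 0.00454). So did oxidative phosphorylation (5.74e-16), the TCA cycle list (3.54e-05) and glycolysis (0.0362). None of these except the FoxO list had passed with an estimated correlation and no covariate (0.171 for cholesterol, 0.514, 0.187 and 0.362). The heat shock (0.227), beta cell identity (0.109) and cytokine lists (0.0525) did not, nor did the ER stress list, whose test then pointed up (0.607). Of the clock genes, Dbp (0.90 ± 0.29) and Bhlhe41 (0.26 ± 0.07) were higher in mean level. Per1 (-0.63 ± 0.21), Cry2 (-0.63 ± 0.13) and Nfil3 (-0.98 ± 0.32) were lower (2 higher and 4 lower adjusted over the list alone). The calls of Dbp, Per1 and Nfil3 lay near the threshold (adjusted p = 0.0468, 0.0489 and 0.0472) and were lost in 37, 42 and 40 of 58 alternatives, of which 22, 28 and 25 left out a single library. On the summed pairs 0 of 19 clock genes passed with edgeR. The cold-inducible genes Cirbp (0.59 ± 0.10) and Rbm3 (chromosome X, 8138975 to 8145880, 0.37 ± 0.11) were both higher. Of 12 housekeeping controls 2 were higher (2 adjusted over the list alone), Ywhaz (0.22 ± 0.05) and Ppia (0.36 ± 0.11), and RLE scaling moved the fold changes of named genes in this comparison by 0.01. The housekeeping list had a camera adjusted p = 0.0169, and adjusted p = 0.365 with an estimated correlation.

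In total 1495 genes (10.3%) passed, 582 higher and 913 lower, 317 of them by at least 1.5-fold. Without CD CT8-1 the count was 2407, and without both CD libraries of 8 h it was 6302. With the pairs summed 6 genes passed and 1780 at an unadjusted p under 0.05. They were Ctgf (-0.99, adjusted p = 0.0407), Slc2a4rg-ps (-0.61) and, chosen after their values were seen, Tbx6 (-1.21), Jsrp1 (-2.25), Lrrc3b (0.83) and Gm14085 (1.37). Of these Jsrp1 was not among the 14454 genes tested. Camera on the summed pairs called the FoxO (2.99e-07), heat shock (1.18e-08), cholesterol (8.12e-08), beta cell identity (0.00829) and cytokine lists (0.0107) at the preset correlation. With an estimated correlation over all libraries the heat shock, cholesterol and cytokine lists did not pass (0.187, 0.171 and 0.087), and the identity list did not with the acinar score as a covariate (0.109).

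Of the 486 genes called between CD and CON, 347 (71.4%) were called in the opposite direction between CD-tRF and CD. These were 207 genes higher in CD than in CON and lower in CD-tRF than in CD, such as Errfi1, Ctgf, Nfkbiz and Cdkn1a, and 140 genes of the reverse order, such as Srebf1, Mpp3, Mnx1 and Pdx1. Of the 347 genes 4 were also called between CD-tRF and CON. Both comparisons share the CD libraries, so their fold changes oppose each other without any effect. Independent lists gave expectations of 18.7 and 7.65 genes. The fold changes correlated with r = -0.70 across genes, which are not independent replicates, with a covariance of -0.0411. Simulated unchanged groups, drawn without a level shared within a group and time, gave 0 opposed genes, r = -0.50 and a covariance of -0.0101, a difference of -0.0309. Exchanges of pairs among the groups within times had medians of 0 opposed genes, r = -0.56 and a covariance of -0.0199, a difference of -0.0212, and their lowest covariance of -0.069 lay beyond the observed one. With the CD libraries split by replicate number 90 and 25 genes were opposed (covariance -0.034 and -0.0385), and with the CD libraries split by time 62 and 102 were opposed, where the covariance was 0.00984 and 0.0186. In the first split by time 47 genes were higher and then lower and 15 the reverse, against 22.8 and 25.8 for independent lists, and in the other split 72 and 30, against 32.5 and 12.5. With the pairs summed 0 genes were opposed by edgeR, among 1 and 6 called in the 2 comparisons.

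The comparison of CD-tRF with CON asked which mean levels under constant light with the feeding window differed from untreated mice. Arhgap36 was higher, at 14.1 CPM against 9.97 CPM (0.51 ± 0.07, adjusted p = 0.00135, n = 12 each), as was Gas2, a cytoskeletal protein gene (0.34 ± 0.06, 0.00633). Lars2 (chromosome 9, 123366927 to 123462666), the mitochondrial leucyl-tRNA synthetase gene, was 3.66-fold higher with a wide spread, at 522 ± 415 against 145 ± 39.9 CPM (0.0197). Its log2 change fell from 1.87 to 0.153 without the libraries numbered 1, and its call was lost in 6 of 58 alternatives. Further, the growth factor gene Igf2 was higher by 0.39 ± 0.09. Lower in CD-tRF were Slc6a9 (chromosome 4, 117834506 to 117875198), a glycine transporter gene, by -0.60 ± 0.10, Pyroxd2 by -0.46 ± 0.08, Slc27a3, a fatty acid transport protein gene, by -0.43, and Tchp by -0.35 ± 0.06 (0.00343). Of the genes named in this paragraph only Lars2 passed with the pairs summed.

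By list, camera called 13 of 29 lists at the preset correlation and 0 with an estimated one, and not all of them are described here. Of 23 genes of cholesterol synthesis 0 passed with edgeR (6 higher adjusted over the list alone, 10 at an unadjusted p under 0.05). Their median was 0.19, with a camera adjusted p = 1.57e-06, against adjusted p = 0.21 with an estimated correlation. The acinar markers had a median of -1.31, with 0 of 26 passing (8 at an unadjusted p under 0.05, camera adjusted p = 5.42e-19, adjusted p = 0.21 with an estimated correlation). For the FoxO and glucocorticoid targets, heat shock and beta cell identity genes, 0 passed with edgeR (2, 2 and 5 at an unadjusted p under 0.05), and the lists did not pass camera (adjusted p = 0.911, 0.121 and 0.115). With 3 libraries left out the heat shock list passed camera as lower (0.0085). List members that passed were Mlxipl (-0.26 ± 0.07), which encodes the glucose-responsive factor ChREBP, the collagen gene Col1a1 (-0.96 ± 0.22) and the cystine transporter gene Slc7a11 (-0.73 ± 0.18). In total 171 genes (1.18%) passed, 40 higher and 131 lower, 27 of them by at least 1.5-fold. With the pairs summed 2 passed and 708 at an unadjusted p under 0.05, Lars2 (1.84, adjusted p = 0.0103) and Btg3 (2.07, chosen after its values were seen), and leaving out single libraries gave 58 to 268 genes.

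The comparison in INS-1 cells asked which genes changed when Dbp was reduced. Dbp had 2290, 2681 and 2215 counts in the scramble libraries (55.5, 54 and 57.3 CPM). It had 256, 280 and 247 counts in the Dbp siRNA libraries (6.45, 7.47 and 6.79 CPM), a log2 change of -3.08 ± 0.07 (edgeR adjusted p = 5.88e-11, n = 3 each). The splicing factor gene Hnrnpm was lower by -2.22 ± 0.05, at 128 against 596 CPM, and Ptprn, the gene of the dense-core granule protein IA-2, by -1.78 ± 0.04, at 207 against 708 CPM. Higher with Dbp siRNA were the chemokine gene Cxcl12, at 97.2 against 20.9 CPM (2.22 ± 0.08), and the immediate early gene Jun, at 54.4 against 19.6 CPM (1.48 ± 0.07). So were the MAP kinase phosphatase gene Dusp1, at 123 against 49.1 CPM (1.33 ± 0.05), and the pro-apoptotic gene Hrk (1.57).

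Many but not all listed genes of hormone processing and exocytosis were lower with Dbp siRNA. Of 17 prohormone processing and granule genes 14 were lower and 0 higher (14 adjusted over the list alone), including the convertase Pcsk2 (-0.93 ± 0.05), the chromogranin family gene Chgb (-0.70 ± 0.05) and the amidating enzyme gene Pam (-0.54 ± 0.04). This granule list had a camera adjusted p = 6.23e-14, and adjusted p = 0.17 with an estimated correlation. Of 22 genes of insulin granule exocytosis 13 were lower and 3 higher (the same numbers adjusted over the list alone), with the calcium sensor Syt7 at -1.30 ± 0.05, Snap25 at -0.42 ± 0.04 and Vamp2 at -0.31 ± 0.04. Exocytosis genes had a camera adjusted p = 0.00308, and adjusted p = 0.17 with an estimated correlation. Of 20 beta cell identity genes 9 were lower and 2 higher (10 and 2 adjusted over the list alone), with Sytl4 at -0.98 ± 0.06, Nkx2-2 at -0.84 ± 0.07, Mnx1 at -0.76 ± 0.05 and the zinc transporter Slc30a8 at -0.66 ± 0.05. Identity genes had a camera adjusted p = 0.00308, and adjusted p = 0.31 with an estimated correlation. Of 7 alpha cell markers 6 were lower (6 adjusted over the list alone), with Gcg, the glucagon gene, at -1.85 ± 0.10. The alpha cell list had a camera adjusted p = 4.15e-05, and adjusted p = 0.17 with an estimated correlation.

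Of 15 measured clock genes 5 were higher and 5 lower (5 and 5 adjusted over the list alone, camera adjusted p = 0.241). The higher ones were Npas2 (0.61 ± 0.15), Nfil3 (0.55 ± 0.06), Tef (0.24), Cry1 (0.24) and Bhlhe40 (0.23), and the lower ones Dbp, Per3 (-0.41), Ciart (-0.35), Per1 (-0.28) and Nr1d2 (-0.24). The call of Ciart lay near the threshold (adjusted p = 0.0499) and was lost in 9 of 12 alternatives, of which 5 left out a single library. Of 19 interferon response genes 7 were higher and 2 lower (7 and 2 adjusted over the list alone), with Usp18 at 1.80 ± 0.14 and Mx2 at 1.67 ± 0.12 (camera adjusted p = 0.0897). Of the other lists, oxidative stress response genes went both ways (8 higher and 6 lower of 21, as adjusted over the list alone, camera adjusted p = 0.182). Immediate early genes did too (6 and 6 of 20, as adjusted over the list alone, 0.248), with Nr4a1 at -1.09 and Atf3 at 0.84. Further, 11 of 24 genes of the TCA cycle and pyruvate metabolism were lower and 3 higher (12 and 3 adjusted over the list alone, 0.182). In total 5075 of 11713 genes (43.3%) passed, 2497 higher and 2578 lower, 1084 of them by at least 1.5-fold. A test against a 1.5-fold change called 301 genes.

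**Figure D5:**
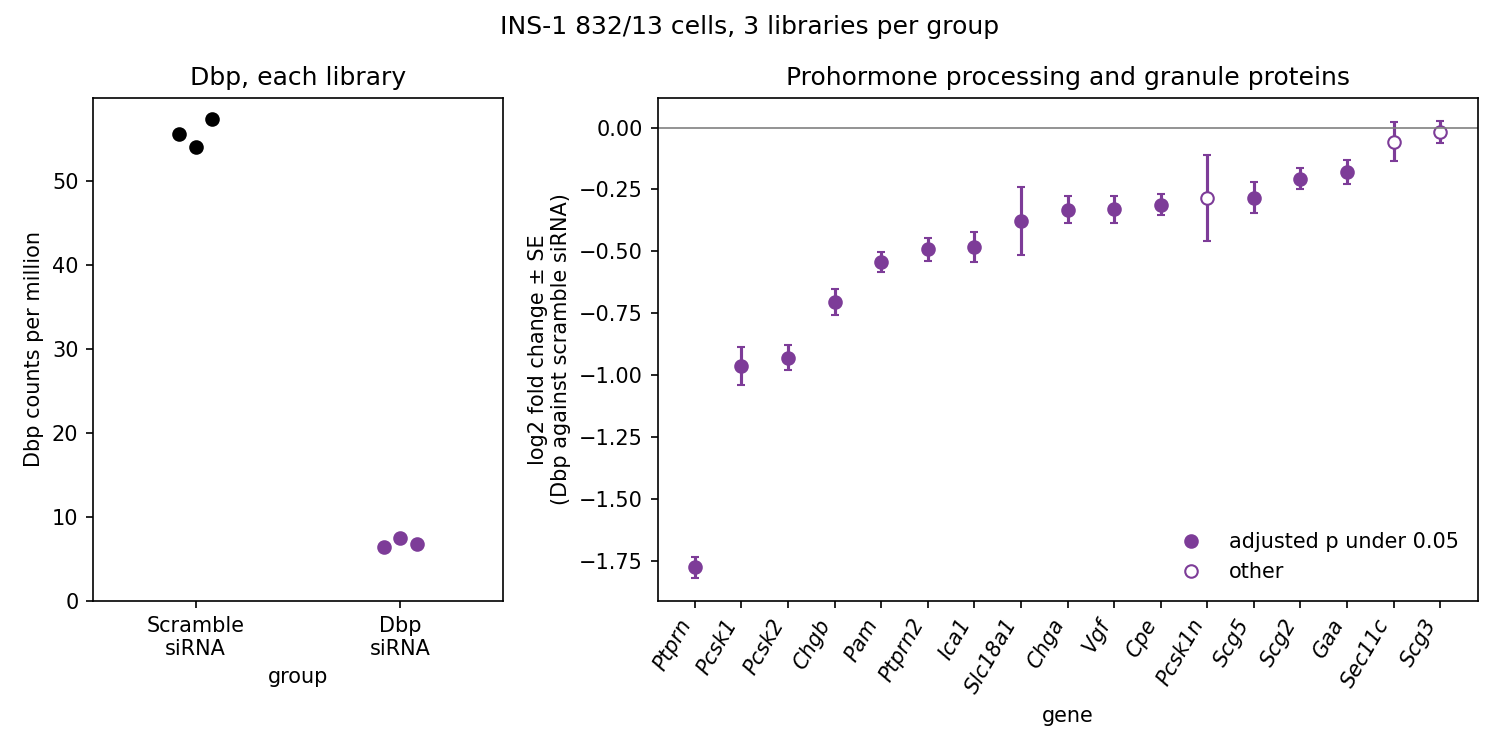
Left, CPM of Dbp in each of the 6 INS-1 libraries. Right, log2 fold change with Dbp siRNA of the 17 prohormone processing and granule genes, with standard errors, where filled points passed at an FDR of 0.05. Dbp is at 54 to 57.3 CPM in the scramble libraries and 6.45 to 7.47 CPM in the Dbp siRNA libraries.

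The genes changed by Dbp siRNA were also compared with the islet groups, over 9887 genes measured in both species under the same symbol. A shared shift of the genes higher or of those lower with Dbp siRNA was not called in any islet comparison (camera adjusted p = 0.991 in all 6 tests, and at least 0.798 with an estimated correlation). Among genes lower in CD-tRF than in CD, 150 were higher with Dbp siRNA against 119 for independent lists (Fisher's exact test, adjusted p = 0.0133), and the other overlaps had an adjusted p of at least 0.103. In the same list 113 were lower with Dbp siRNA, against 127. The test treats genes as independent and makes no allowance for level. Genes called with Dbp siRNA had a median mean log2 CPM of 5.58, against 4.71 for the others. As many genes were called between CD-tRF and CD in 8 of 32 exchanges of library pairs, so chance cannot be excluded for that list.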

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

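The tests of exocrine RNA, of transcript length, of libraries deposited in duplicate and of time of day were chosen after the results were seen, and the regroupings of libraries and times were planned. The rhythm of 254 genes differed between CD and CON, and 15 of them were core clock genes. The rhythm of 1233 genes differed between CD-tRF and CD, 17 of them core clock genes, and that of 4 genes differed between CD-tRF and CON. Each of these values was singled out because a test of the difference between groups passed.

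Libraries were regrouped at random within the 24 libraries of each comparison. In 1 of 40 groupings, the real one, as many genes differed in mean level between CD and CON (486, highest other 1), between CD-tRF and CD (1495, highest other 1) and between CD-tRF and CON (171, highest other 0). By the set bound these counts lie outside regroupings of single libraries. Such regroupings break up the pairs of like libraries, which moves a level shared by a pair into the spread and lowers the counts. They cannot exclude chance at the level of pairs. The rhythm difference between CD and CON was also reached by 1 of 40 (254, highest other 44). In contrast 4 of 40 groupings reached that between CD-tRF and CD (1233, highest other 7907) and 3 of 40 that between CD-tRF and CON (4, highest other 3775), and chance cannot be excluded there. When whole pairs of a group and time were exchanged between the groups within a time, 6 of 32 exchanges gave as many genes for CD against CON (486, highest other 6503). The number was 8 of 32 for CD-tRF against CD (1495, highest other 8067) and 1 of 32 for CD-tRF against CON (171, highest other 20). Chance at the level of pairs cannot be excluded for CD against CON or for CD-tRF against CD. For CD-tRF against CON the share was under 0.05, but 1 of 32 is the smallest share that these exchanges can give. The shares were not adjusted for the number of tests, and with the pairs summed only Lars2 and Btg3 passed. Chance is therefore not firmly excluded for that comparison either. For the rhythm differences, 16 of 32 exchanges reached 254 (highest other 6866), 16 of 32 reached 1233 (highest other 8781) and 18 of 32 reached 4 (highest other 139), so chance cannot be excluded for any of them. Some exchanges called several times the real count, and the source of these counts was not tested.

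When the 6 times were rearranged in all 60 orders, 1 order, the real one, gave as many rhythmic genes in CON (567, highest other 537). The same held for rhythmic clock genes (15, highest other 13). Both shares were under 0.05, the bound set for excluding chance, but were not adjusted for the number of tests. For the total, an order with 537 genes came close, and with the pairs summed only Npas2, Ppp1r3c, Arntl and Nfil3 passed. The total count in CON is therefore not secured by this test. In CD-tRF, 12 orders gave as many rhythmic genes (1773, highest other 4045), so chance cannot be excluded for the total count. For rhythmic clock genes 2 orders gave as many (17, highest other 17), a share under 0.05 that was also unadjusted. In CD, 42 orders gave as many rhythmic genes (45, highest other 3128) and all 60 gave as many rhythmic clock genes (0, highest other 1), which excludes nothing. For the opposed genes, 3 of 40 exchanges of pairs among the 3 groups gave as many (347, highest other 908), so chance cannot be excluded. For Dbp siRNA the 10 splits of 6 libraries are too few for a share under 0.05, with 5075 genes in the real split and 0 in the highest other.

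The acinar level was shared by the 2 libraries of each group and time, with an intraclass correlation of 0.99 (permutation p = 5e-05, the smallest that the permutations can give). A library deposited in duplicate was argued against by the counts, since the lowest chi-square per gene of the 18 pairs was 2.94. Circadian time explained 19.7% of the variance of the score, and rearranged times explained as much with a permutation p of 0.779, so a profile of time of day common to the groups was not seen. Exocrine cells carried along in each islet preparation remain a candidate source, since 96.2% of the 26 acinar markers followed the score of the others with a slope between 0.5 and 1.5. Whether both libraries of a pair came from islets pooled over animals was not tested, and an effect of the treatment on the exocrine share stays open, since the permutation tests between groups did not pass (p = 0.0714, 0.0584 and 0.632).

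The 486 genes called between CD and CON and the 1495 called between CD-tRF and CD were weighed against exocrine RNA and against transcript length. With the acinar score as a covariate 100% and 83.3% of them stayed called, and with the length slope as a covariate 100% and 99.9%. This met the bound set against either as the whole cause of these calls. Each covariate also raised the number of genes called in both comparisons, as given in the next section. A gene could stay called for that reason alone, so the shares decide little. Without the CD pair of 8 h, however, 5069 and 6302 genes were called, of which 29.4% and 40.9% stayed called with the length slope as a covariate. Their median log2 change fell in size from 0.32 to 0.14 and from 0.34 to 0.16, and those higher in CD than in CON had a median transcript length of 5.4 kb and those lower 1.92 kb. Without that pair, the CD libraries other than CT0-2 (-0.072) had length slopes of 0.087 to 0.145. The mean slope was -0.02 in CON and in CD-tRF, so the covariate then largely overlaps with group. Fewer calls would follow from a length bias of libraries and from a true group difference alike, and the test cannot tell them apart. For the genes called with all libraries, exocrine RNA, transcript length and the differences in light and feeding stay open.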

How the results depend on the processing

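Summing pairs, leaving out 3 libraries, the length slope, leaving out the CD pair of 8 h and the split by time were chosen after the data were seen, and the others were planned. Of the values of named genes under all alternatives, 14559 kept their side of the threshold, 758 no longer passed and 96 newly passed. Of the values that passed in the main test 0 changed sign, whereas values that had not passed, such as Npas2 in CD-tRF against CD (-1.22 to 0.287), could take either sign. The values lost in most of their alternatives were Ciart with Dbp siRNA (9 of 12), Per1, Nfil3 and Dbp in CD-tRF against CD (42, 40 and 37 of 58) and the rhythm difference of Apobec1 between CD-tRF and CON (30 of 49). RLE scaling and the stricter filter kept each count within 1.5 times. The cause was not tested unless the setting itself uses fewer libraries. In counts simulated at this depth without a level shared within pairs, the smallest fold change between CD and CON was found for 46% of genes. Changes of that size can therefore be missed. No other depth was simulated, so what more depth alone would add is not known.

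Values are given for the results that moved. Without a filter 285 genes were called between CD-tRF and CON and 23 differed in rhythm between them. DESeq2 called 835 in CD against CON and 361 in CD-tRF against CON, 976 rhythmic in CON and 162 in CD, rhythm differences of 571 (CD against CON), 1988 (CD-tRF against CD) and 23 (CD-tRF against CON), and 539 opposed. Without a time term 266, 45 and 179 were called in CD against CON, CD-tRF against CON and as opposed. Fits to the 2 groups alone gave 828 in CD-tRF against CD and 340 in CD-tRF against CON. With the acinar score as a covariate the group counts were 1685, 7650 and 3592 (CD against CON, CD-tRF against CD, CD-tRF against CON) and the rhythmic counts 967 in CON and 2896 in CD. The rhythm differences were then 1040 (CD against CON) and 15 (CD-tRF against CON), and 1363 were opposed. With time as a 6-level factor 2592, 8046 and 5183 differed between times in any way in CON, CD and CD-tRF. The profile over times then differed between groups for 7590, 9595 and 1093. These tests rest on the spread within pairs and do not ask for a 24 h rhythm. Fits to each group alone gave 2132, 13 and 597 rhythmic genes. Without 0 h the group counts were 125, 968 and 6 with 102 opposed, without 8 h 4133, 5923 and 62 with 3109, and without 12 h 234, 757 and 20 with 167. They were without 16 h 168, 983 and 111 with 119, and without 20 h 122 and 751 with 83, where CD-tRF against CON stayed within 1.5 times.

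With the pairs summed, 1, 6 and 2 were called between groups, 4, 0 and 34 were rhythmic, 1, 5 and 0 differed in rhythm and 0 were opposed. With 3 libraries left out, 2096 were called in CD against CON and 271 in CD-tRF against CON, and 1421 were rhythmic in CON and 3150 in CD-tRF. Then 3068 and 1 differed in rhythm between CD-tRF and CD and between CD-tRF and CON, and 773 were opposed. With the length slope the group counts were 1965, 3690 and 2228, the rhythmic counts 2306, 111 and 4321, the rhythm differences 878 and 2204, and 1136 were opposed. Without the CD pair of 8 h the group counts were 5069, 6302 and 291, 13 were rhythmic in CD, 160 and 721 differed in rhythm from CON and from CD-tRF, and 3820 were opposed. With pairs summed and that CD pair left out, 3353, 4002 and 3 were called and 2378 opposed. The CD libraries split by number gave 90 and 25 opposed genes and split by time 62 and 102. A test against 1.5-fold gave 301 genes with Dbp siRNA. With an estimated correlation 1, 2, 0 and 0 lists were called in the 3 islet comparisons and with Dbp siRNA, against 11, 14, 13 and 4 by camera with the preset value. Fry called 6, 6 and 14 in CD against CON, CD-tRF against CON and Dbp siRNA.

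Replicate numbers 1 and 2 did not pair the islet libraries as a block, since 3 of 18 correlations of same-numbered libraries were over 0.1 (range -0.17 to 0.22). In INS-1 cells the correlations were 0.05, 0.04 and 0.07, although each library correlated best with its own number. With the number as a replicate block 2 genes differed in rhythm between CD-tRF and CON, 5870 were called with Dbp siRNA and other counts stayed within 1.5 times. With the number by time as a block of 12 levels 282 and 49 were called in CD against CON and CD-tRF against CON, and 201 were opposed. Without replicates numbered 1 in the islets the counts were 0, 0 and 0 between groups (edgeR), 4, 0 and 12 rhythmic, 2, 3 and 0 for rhythm differences and 0 opposed. Without those numbered 2 they were 2, 0 and 7, 2, 0 and 21, 0, 14 and 0, and 0, where each group and time keeps 1 library.

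Leaving out each library in turn gave 277 to 1205 genes in CD against CON (277 without CD CT0-1, 304 without CD CT20-1, 833 without CD CT8-2, 1205 without CD CT8-1) and 1165 to 2407 in CD-tRF against CD (2407 without CD CT8-1). In CD-tRF against CON it gave 58 to 268, with 65 without CON CT0-1 or CT0-2, 93 without CON CT8-1, 64 without CON CT8-2, 73 and 74 without CON CT12-1 and CT12-2, and 79 without CON CT16-1. It gave 58 without CD-tRF CT0-1, 70 without CT8-1, 67 and 105 without CT12-1 and CT12-2, 98 and 268 without CT16-1 and CT16-2, and 108 without CT20-1. Rhythmic genes in CON were 334 to 953 (345 without CON CT4-1, 349 without CON CT8-1, 334 without CON CT8-2, 953 without CD-tRF CT4-2). In CD they were 15 to 105 (18 without CD CT8-1, 15 without CD CT8-2, 24 without CD CT20-1, 21 without CD CT4-2, 105 without CD-tRF CT4-2), and in CD-tRF 1340 to 4950 (4950 without CD-tRF CT4-2). Rhythm differences were 172 to 548 between CD and CON (548 without CD-tRF CT4-2) and 776 to 6797 between CD-tRF and CD (776 without CD CT8-1, 805 without CD CT8-2, 808 without CD-tRF CT8-1, 6797 without CD-tRF CT4-2). Between CD-tRF and CON they were 0 to 9: 0 without CON CT0-1 or CD-tRF CT0-1, 9 without CD-tRF CT12-1, and 1 without CON CT4-1 or CT16-2 or CD-tRF CT16-1, CT0-2 or CT12-2. They were 2 without CON CT8-1, CT16-1, CT4-2 or CT8-2, CD CT0-1, CT4-1, CT16-1, CT20-1, CT0-2, CT4-2, CT16-2 or CT20-2, or CD-tRF CT4-1, CT8-1, CT20-1, CT8-2 or CT20-2. Opposed genes were 210 to 741 (210 without CD CT0-1, 225 without CD CT20-1, 567 without CD CT8-2, 741 without CD CT8-1), and genes called with Dbp siRNA were 3961 to 5617.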

Other observations

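The test of thinned libraries, the spread set beside the seed test and the counts without the CD pair of 8 h were chosen after the result was seen, and the tests of seed matches and of gene level were planned. Members of further gene lists differed between CD-tRF and CD islets. Of 28 genes of fatty acid synthesis and oxidation 2 were higher, Scd1, a fatty acid desaturase gene (1.05 ± 0.32), and Srebf1 (0.29), and 1 was lower, Pdk4 (-0.70) (5 higher and 1 lower adjusted over the list alone). The fatty acid list had a camera adjusted p = 0.0455, and adjusted p = 0.216 with an estimated correlation. Of 17 prohormone processing and granule genes 3 were higher, Chga (0.31), Pcsk2 (0.19) and Scg3 (0.18), and 1 was lower, Vgf (-0.27), with 3 and 1 adjusted over the list alone (camera adjusted p = 0.0668). Of 24 exocytosis genes 2 were higher, Cplx2 (0.27) and Vamp2 (0.14), and 1 was lower, Abcc8, the sulfonylurea receptor gene (-0.29), with 6 and 2 adjusted over the list alone (camera adjusted p = 0.25). Of 42 histone and chromatin regulators 2 were higher, the deacetylase genes Hdac1 (0.21) and Hdac3 (0.23), and 1 was lower, with 2 and 1 adjusted over the list alone (camera adjusted p = 0.376). This balance changed with the setting: 4 were higher and 21 lower without the CD pair of 8 h, and with the acinar score as a covariate camera called the list as lower (3.54e-05). Of 22 oxidative stress genes Slc7a11 (-1.26 ± 0.18) and Txnip (-0.87 ± 0.17) were lower, with 2 adjusted over the list alone, while the list's test pointed up (camera adjusted p = 0.23). Of 21 interferon response genes Irf9 (-0.46) and Stat2 (-0.19) were lower, with 1 adjusted over the list alone (0.981), and of 19 immediate early genes Klf6 was lower (-0.44), with 1 adjusted over the list alone (0.69).

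Among other cell types, 2 of 10 ductal markers were lower in CD-tRF than in CD, Muc1 (-1.22 ± 0.20) and Spp1 (-0.67 ± 0.13), with 2 adjusted over the list alone (camera adjusted p = 0.376). Of 16 fibroblast and stellate cell markers the collagen genes Col1a1 (-0.85) and Col1a2 (-0.43) were lower and Col6a3 was higher (0.62), with 4 and 1 adjusted over the list alone (0.102). Tek was lower among 15 endothelial markers (-0.32), with 1 adjusted over the list alone (camera adjusted p = 0.0495, adjusted p = 0.449 with an estimated correlation). C1qa was higher among 15 macrophage markers (0.50), with 0 adjusted over the list alone (camera adjusted p = 0.023, adjusted p = 0.449 with an estimated correlation). In CD against CON, single members of further lists passed. The oxidative stress gene Txnip (0.79 ± 0.17; 2 of 22 adjusted over the list alone), the immediate early gene Klf6 (0.37 ± 0.10; 1 higher and 1 lower of 19), the alpha cell gene Wnk3 (0.57 ± 0.16; 1 and 1 of 11) and the cell cycle gene Tk1 (0.56; 1 of 28) were higher. The glycolytic gene Pfkl was lower (-0.20 ± 0.06; 3 of 18 adjusted over the list alone), with a camera adjusted p = 0.000722 and adjusted p = 0.203 with an estimated correlation. For oxidative phosphorylation the test pointed down with 0 of 35 called by edgeR and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.00831, adjusted p = 0.872 with an estimated correlation). Without the CD pair of 8 h, 23 of these 35 genes were lower in CD than in CON and 34 were higher in CD-tRF than in CD. In that setting, where calls followed transcript length, 29.4% and 40.9% of all called genes stayed called with the length slope as a covariate. The cold-inducible Cirbp was rhythmic in every group, with amplitudes of 0.40 in CON, 0.51 in CD and 0.56 in CD-tRF and peaks at 5.3, 6.5 and 2.8 h (adjusted p = 0.0257, 0.0151 and 0.000475). Rbm3 had amplitudes of 0.54, 0.40 and 0.29 (0.000376, 0.0444 and 0.0492). Of these 2 genes 1 differed in rhythm between CD and CON and 1 between CD-tRF and CD. With the pairs summed neither gene was called rhythmic in any group. The total of rhythmic genes in CD was reached in 42 of 60 orders of the times.

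A list's median and mean, or either and its test, differed in sign in some cases. In CD against CON this held for exocytosis (median -0.05, mean 0.01, test down), the oxidative stress response (-0.05, 0.01, down), fatty acid genes (-0.03, 0.06, down), ductal (-0.07, 0.05, up) and delta cell markers (-0.04, 0.02, up). It also held for cell cycle, Schwann and fibroblast lists, whose median and mean were positive and whose test pointed down. In CD-tRF against CD it held for exocytosis, interferon and ductal genes, in CD-tRF against CON for glycolysis, FoxO, cytokine and pancreatic polypeptide cell lists, and with Dbp siRNA for disallowed, oxidative stress, immediate early, fatty acid and fibroblast genes. Fry's mixed test, which asks for change in either direction, called 6, 14 and 0 of 29 lists in CD against CON, CD-tRF against CD and CD-tRF against CON and all 25 lists with Dbp siRNA.

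The breadth of the change with Dbp siRNA, 5075 genes, was weighed against seed matches of the siRNA and against depth. Over 15573 words of 7 bases in 3' UTRs of 10995 genes (93.9% of those tested), with mouse sequence standing in for rat, the most negative t of a word's link to lower expression was -4.43 and the most positive 4.57. This met the bound set for excluding seed matches, but the 2 sizes differ by less than the spread of a t and the species is a stand-in, so seed effects stay open. The word with the most negative t did not occur in the mouse Dbp transcript. Of the 20 most negative words 1 occurred there, against 2.03 expected. A difference in depth was argued against by 96.7% of the called genes staying called with all libraries thinned to 36.4 M counts, while the median mean log2 CPM of 5.58 for called genes against 4.71 for the others decides little, since power rises with level. A response of many genes to the loss of Dbp or to that siRNA may account for the rest and was not tested further.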
